A study of Homo sapiens with 12 samples.

How the data were processed

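The series holds 12 human samples from 3 established cell lines: H1 embryonic stem cells, IMR90 lung fibroblasts and Saos-2 osteosarcoma cells. DNA labelled with the thymidine analogue bromodeoxyuridine (BrdU) was pulled down with a BrdU antibody and sequenced in 4 samples, and chromatin carrying H3K18ac, the acetylation of a lysine in the tail of histone H3, was immunoprecipitated and sequenced in 2 samples. The remaining 6 samples are inputs without a region list, and their signal was not analysed here. Per the labels, each BrdU pull-down started from 4 µg of labelled DNA, which was treated with alkali to remove RNA primers, sonicated, denatured and, after the pull-down, made double-stranded by random priming. The H1 cells for BrdU sequencing received either a non-targeting siRNA or siRNAs against EP300 and CREBBP, with a further additive in the medium of both cultures that the labels give for neither H3K18ac nor the other cell lines, and were collected 72 h later. Each H3K18ac immunoprecipitation used 5000000 cells. IMR90 and Saos-2 cells, and the H1 cells for H3K18ac, received no siRNA, so comparisons of H1 BrdU regions with these lists also differ in treatment.

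The deposited files are 6 lists of regions, 1 per pulled-down library. The submitters' processing notes name Bowtie 0.12.7 and the genome build hg19. The region caller, its threshold, the handling of duplicate reads and the use of the input libraries are not given in the sources used here. Every region lies on a grid of 100 bp windows, with both ends included, and no 2 regions of a list lie closer than 300 bp. The last column was taken as a score given by the authors, and its meaning is not stated in the deposited files. It is a whole number per region that grows with the length of the region (Spearman correlation across regions from 0.502 in the H1 knockdown list to 0.957 in the IMR90 H3K18ac list), so it was used only to rank regions within their own list and never compared between lists. No read counts or library sizes were used, so the depth of each library is unknown, and a region absent from a list may have lain just under the authors' threshold.

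Regions were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A region counted as shared when at least 1 bp of it lay in a region of the other list. Each share is given with its Wilson 95% confidence interval, which covers the counting error of regions only. Neighbouring regions are not independent, and between libraries there is no replicate error to set beside it. Each overlap was divided by the mean of 1000 random placements of the regions, at their own lengths, on their own chromosome, outside 500 kb bins that held no region in any list. This left 5587 bins, or 2794 Mb, open to placement. The interval of a fold is the interval of the share divided by the mean random share. For comparisons across the 3 cell lines, overlapping regions of the lists were merged into loci, and regions of a list were classed by the number of other cell lines with an overlapping region. Lists were also divided by score into 5 equal groups (score bins). Control regions in H1 were called kept when a knockdown region overlapped them and lost otherwise.

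With 1 library in each group, no test between conditions was possible and no p-values are given. The comparisons made were H1 knockdown against H1 control, the BrdU lists across cell lines, H3K18ac in H1 against IMR90, H3K18ac at BrdU regions, and H3K18ac at control regions kept or lost after the knockdown. The regions named in the text were taken from the 10 of highest score in each set, that is, those of each list with an overlap in the other list and those without one. The comparisons, this rule and most of the alternatives were fixed before the data were examined. The alternatives were an overlap of at least 50% of the region, stricter lists with the upper 50% of regions by score, merging of regions within 10 kb, autosomes only, random shifts of up to 1 Mb in place of placement along the chromosome, lists of equal number, windows of 2 kb around region midpoints, and a distance of 10 kb for lost regions. For lists of equal number, the longer lists were cut to their regions of highest score. Alternatives used 300 random placements each. The overlap code was tested on simulated lists in which 20% of the regions had been planted, and it recovered between 19.9% and 20.1%.

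No gene annotation of hg19 was used here, so regions are given by chromosome, start and end without gene names. A planned count of regions at the members of 14 gene lists was for the same reason not run. Counts for single chromosomes are restricted to autosomes. EP300 and CREBBP levels after the siRNA treatment were not analysed here.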

Results

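DNA synthesis was mapped by BrdU sequencing in H1 embryonic stem cells, IMR90 fibroblasts and Saos-2 osteosarcoma cells, and H3K18ac by chromatin immunoprecipitation in H1 and IMR90, to relate replication to an epigenetic mark. EP300 and CREBBP, the paralogous acetyltransferases p300 and CBP that acetylate H3K18, were knocked down together in one H1 culture. Each of the 6 groups had 1 library, so no difference between groups could be set against the spread of replicates. The BrdU lists held 5086 regions in H1 with non-targeting siRNA (H1 control), 1755 in the H1 knockdown, 5743 in IMR90 and 6272 in Saos-2. They covered 1.08, 0.211, 1.22 and 2.06 Mb of the genome, respectively. The H3K18ac lists were larger, with 65946 regions over 15.7 Mb in H1 and 84471 regions over 39.5 Mb in IMR90. Most BrdU regions were small: the median length was 100 bp, a single window, in both H1 lists and in IMR90, and 200 bp in Saos-2.

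**Figure D1:**
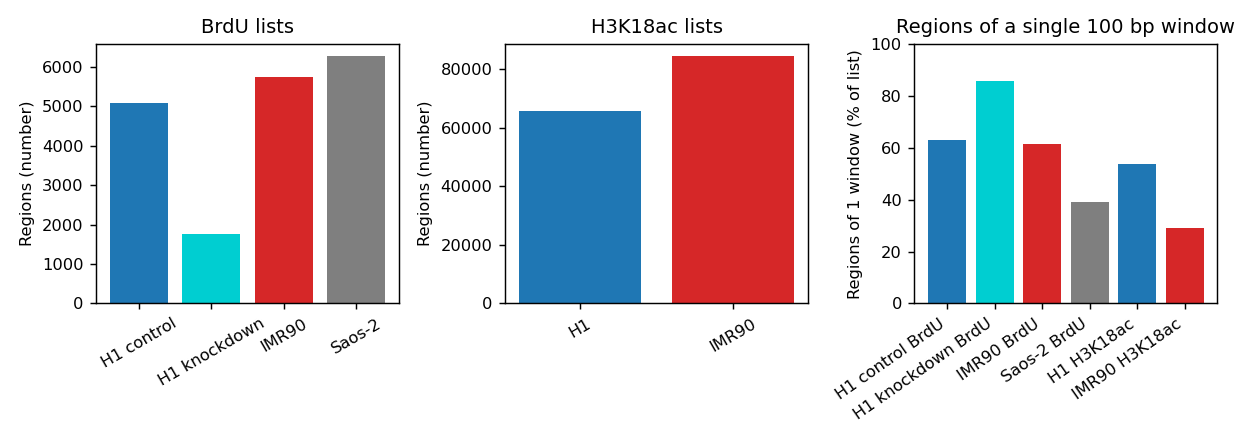
Number of regions in each BrdU list (left) and each H3K18ac list (middle), and the percent of regions in each list that span a single 100 bp window (right), with 1 library per bar. The H1 knockdown list has the fewest regions, 1755, and the highest share of single-window regions, 85.8%.

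The first comparison asked how the replication map of H1 changed when EP300 and CREBBP were knocked down. The knockdown list held 0.345 times as many regions as the control list and covered 0.196 times its length. Its regions were also shorter, with a mean length of 120 bp against 212 bp, and 85.8% of them spanned a single window against 62.9% in the control. The longest knockdown region measured 700 bp and the longest control region 3400 bp. Of the 5086 control regions, 156 (3.07%, 95% interval 2.63 to 3.58) overlapped a knockdown region, and 159 of the 1755 knockdown regions (9.06%, 7.80 to 10.5) overlapped a control region. Both shares were far above random placement, by 201-fold and 110-fold. These folds were 108 and 69.3 with random shifts within 1 Mb, 74.7 and 62.5 after merging within 10 kb, and 447 and 298 in the lists of the upper 50% by score.

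Regions with high control scores were retained more often, yet most of them were also missing from the knockdown list. The share of control regions overlapped by the knockdown list was 0 of 1018 in the lowest of 5 score bins and 11.1% (9.32 to 13.2) in the highest, and 34 of the 100 highest-scoring control regions were found. Regions of the highest bin were also longer, with a median of 500 bp against 100 bp, and when only the central window of each region was compared, 3.54% of them overlapped. The 4 control regions of highest score had no knockdown counterpart. They lay on chromosome 22 at 50775501 to 50778900, on chromosome 12 at 123994901 to 123997700, on chromosome 1 at 41991901 to 41994900 and on chromosome 2 at 239393701 to 239395800. All 4 were present in IMR90 and in Saos-2, and all 4 overlapped H3K18ac in H1. The next 2 regions by score were kept: chromosome 12 at 132640301 to 132642900, which was reduced to a knockdown region at 132640701 to 132641000, and chromosome 19 at 35788101 to 35790000, reduced to 35789601 to 35789800. Over the 156 kept regions, knockdown regions covered 25.4 of the 101 kb in the control list, or 25.1%. Of the 10 highest-scoring knockdown regions without a control counterpart, 8 were in the Saos-2 list, such as chromosome 1 at 6234801 to 6235200. The 100 highest-scoring knockdown regions overlapped the control list in 76 cases and the Saos-2 list in 88. The Saos-2 list covered 1.91 times the length of the control list. Relative to random placement, the whole knockdown list overlapped H1 control 110-fold and Saos-2 80.5-fold.

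**Figure D2:**
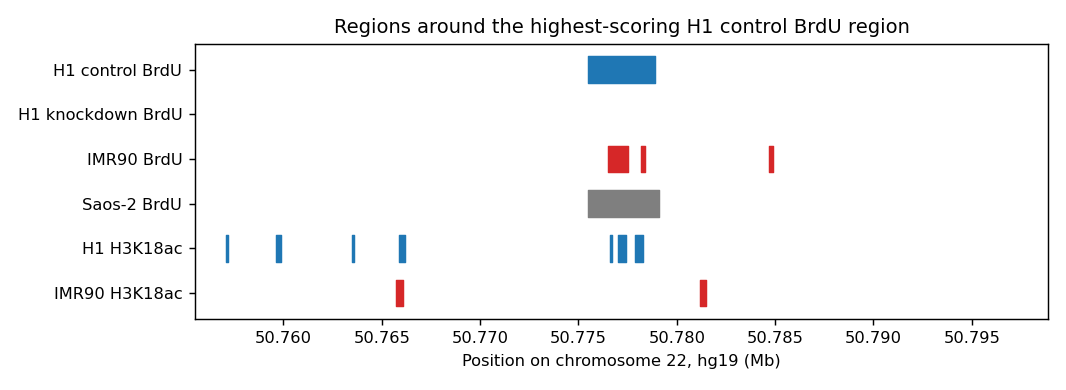
Regions of all 6 lists within 20 kb of the highest-scoring H1 control BrdU region, on chromosome 22 at 50775501 to 50778900 (hg19), with position in Mb on the horizontal axis and 1 list per line. The H1 control and Saos-2 lists each hold 1 region here, of 3400 and 3600 bp, and the knockdown list holds 0.

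The second comparison asked to what extent the 3 cell lines replicated at the same places. Strong BrdU regions were shared between cell lines far more often than weak ones, to a degree that differed between the lists. Of the H1 control regions, 1044 (20.5%, 19.4 to 21.7) overlapped a region in IMR90 and 1727 (34.0%, 32.7 to 35.3) a region in Saos-2. Of the IMR90 regions, 18.1% overlapped H1 control and 26.8% Saos-2, and of the Saos-2 regions, 26.0% overlapped H1 control and 23.5% IMR90. These 6 overlaps were between 128 and 243 times the mean of random placement, between 46.9 and 95.1 times with random shifts within 1 Mb, and between 51.0 and 84.2 times after merging within 10 kb. Merging the 3 lists gave 13567 loci, of which 926 (6.83%) were found in all 3 cell lines. Loci found in 1 cell line numbered 3163 for H1, 4026 for IMR90 and 4059 for Saos-2. With 1 library per group, it is unknown how many of these would recur in the same cell line. Of the 2035 H1 control regions in the lower 2 score bins, 22 (1.08%) overlapped any other BrdU list. H1 shared more loci with Saos-2 alone (712) than with IMR90 alone (148). The Saos-2 list covered more of the genome, and relative to random placement H1 control overlapped IMR90 more (243-fold) than Saos-2 (171-fold), an order that turned when regions within 10 kb were merged (69.2-fold and 75.2-fold). With lists of equal number the shares of H1 control regions stayed at 20.5% in IMR90 and 33.6% in Saos-2, at 252-fold and 200-fold.

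The shared regions were those of high score. In the lowest bin of the H1 control list 0 of 1018 regions overlapped Saos-2, and in the highest 3 bins, in rising order, 13.2%, 60.4% and 95.7% did. The share in IMR90 rose from 0.196% in the lowest bin to 61.8% in the highest. At the central window alone, the highest bin reached 88.8% in Saos-2 and 46.6% in IMR90. The highest IMR90 bin overlapped H1 control in 64.6% and Saos-2 in 84.1%, or 47.2% and 72.2% at the central window. The highest Saos-2 bin overlapped H1 control in 71.1% and IMR90 in 53.7%, or 47.4% and 34.9% at the central window. The difference between high and low bins of H1 control was also present at equal length. Among regions of a single window, 284 of 434 (65.4%) overlapped Saos-2 in the second highest bin and 0 of 1016 in the lowest. Of the 100 highest-scoring regions in H1 control, 100 were present in Saos-2 and 81 in IMR90. The region on chromosome 1 at 41991901 to 41994900, ranked 3 by score in H1 control, coincided with the highest-scoring IMR90 region at 41991801 to 41995200. The highest-scoring H1 control region absent from IMR90 was that on chromosome 19 at 35788101 to 35790000, ranked 6 by score in its list. The highest-scoring H1 control region absent from Saos-2, on chromosome 5 at 5305001 to 5305500, ranked only 214 in its list. The highest-scoring Saos-2 region absent from H1 control lay on chromosome 5 at 648401 to 651400 and was also found in IMR90. With the upper 50% of each list by score, the share of H1 control regions in Saos-2 rose to 60.0% and that in IMR90 to 39.4%.

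**Figure D3:**
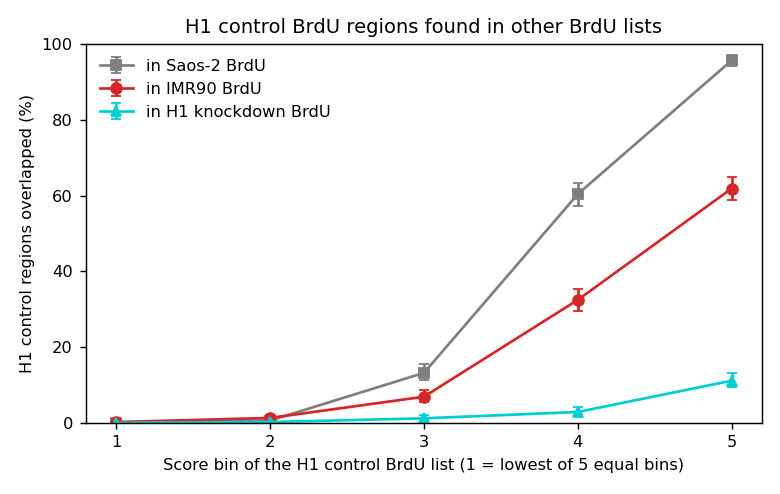
Percent of H1 control BrdU regions that overlap a region of the Saos-2, IMR90 or H1 knockdown BrdU list, for 5 equal bins of the control list by score, with Wilson 95% intervals as error bars. In the highest bin 95.7% of regions are found in Saos-2, 61.8% in IMR90 and 11.1% in the knockdown.

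The third comparison set the H3K18ac lists of H1 and IMR90 side by side, as the mark is laid down at active promoters and enhancers that differ between cell types. The IMR90 list was 1.28 times as long by number and 2.51 times by covered length, with a median region of 300 bp against 100 bp in H1. Of the H1 regions, 12502 (19.0%, 18.7 to 19.3) overlapped an IMR90 region, which was 9.72 times the random mean, and 12289 IMR90 regions (14.5%) overlapped an H1 region. The share rose with score from 5.45% to 51.6% between the lowest and highest score bins in H1 and from 4.97% to 25.0% in IMR90. Median length rose along with it, from 100 to 500 bp in H1 and from 100 to 1000 bp in IMR90. Compared at the central window alone, the highest bin reached 35.8% in H1 and 11.5% in IMR90, the latter below the 12.8% of the bin before it. The highest-scoring H1 region, on chromosome 7 at 104652401 to 104656000, was shared and overlapped an IMR90 region at 104653301 to 104656300. The second, on chromosome 21 at 9825401 to 9826800, was absent from IMR90, as was a region of 4200 bp on chromosome 2 at 233283201 to 233287400. The region on chromosome 21 also overlapped a region of the Saos-2 BrdU list. Repeats and regions prone to artefacts were not filtered out for the comparisons. The 2 highest-scoring IMR90 regions were absent from H1. They lay on chromosome 17 and formed broad blocks, of 26800 bp at 46644201 to 46671000 and of 14700 bp at 48262801 to 48277500. A further IMR90 block without an H1 counterpart spanned 9200 bp on the same chromosome at 59477601 to 59486800. When regions within 10 kb were merged, the share of IMR90 regions overlapped by H1 rose to 36.5%, while the fold over random placement fell from 9.44 to 3.60, and from 9.72 to 3.58 for H1 regions in IMR90.

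The fourth comparison asked whether H3K18ac lay at replicating loci of the same cell line. In H1, 445 of the 5086 control BrdU regions (8.75%, 8.00 to 9.56) overlapped an H3K18ac region, 7.88 times the random mean (7.21 to 8.61). The H1 H3K18ac list overlapped the BrdU regions of the other cell lines as much or more: 9.49% (8.76 to 10.3) in IMR90, at 7.84-fold, and 12.6% (11.8 to 13.4) in Saos-2, at 8.28-fold. In IMR90 the direct overlap was close to random placement. The IMR90 H3K18ac list, which covers more of the genome, overlapped 140 IMR90 BrdU regions (2.44%, 2.07 to 2.87), at 1.28-fold (1.09 to 1.51), and 120 H1 control regions (2.36%), at 1.29-fold. When regions were shifted at random within 1 Mb in place of placement along the chromosome, the fold fell to 4.18 for H1 control in H1 H3K18ac and to 0.912 for IMR90 BrdU in IMR90 H3K18ac. For the latter it was 0.911 in the stricter lists but 1.58 in 2 kb windows around the BrdU midpoints and 1.57 within 1 kb, so the small excess in IMR90 depended on the setting.

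H3K18ac in H1 was most frequent at BrdU regions common to the cell lines. Of the H1 control regions found in all 3 cell lines, 24.4% (21.6 to 27.4) overlapped H1 H3K18ac, against 14.2% of those found in 1 other cell line and 2.69% (2.18 to 3.31) of those found in H1 alone. These classes also differed in median length, at 400, 200 and 100 bp, and in median score, at 649, 250 and 39. Relative to random placement at the same lengths the folds were 12.7, 10.6 and 3.28. BrdU regions found only in IMR90 or only in Saos-2 overlapped the H1 H3K18ac list in 5.29% (4.64 to 6.03) and 6.78% (6.04 to 7.59), both above the share for H1 alone. The IMR90 H3K18ac list did not have this order, and its folds were highest at regions found in 1 cell line alone. It overlapped 2.00% of the H1 control regions found in all 3 cell lines, at 0.768-fold (0.481 to 1.22). Of those found in 1 other cell line it overlapped 1.86%, at 0.912-fold (0.592 to 1.40). Of those found in H1 alone it overlapped 2.62%, at 1.67-fold (1.35 to 2.07). These shares lay within counting error of each other. For IMR90 BrdU regions the folds were 0.742 (0.465 to 1.18) in all 3 cell lines, 0.612 (0.342 to 1.09) in 1 other and 1.63 (1.36 to 1.95) in IMR90 alone. For Saos-2 BrdU regions they were 0.830, 0.827 and 1.38 in the same order. The 4 highest-scoring H1 control regions all overlapped H1 H3K18ac. Within the region on chromosome 22 at 50775501 to 50778900, for example, an H3K18ac region lay at 50777001 to 50777400. Those ranked 5 and 9 by score, on chromosome 12 at 132640301 to 132642900 and on chromosome 6 at 34039101 to 34041000, did not. Seen from the mark, 472 of the 65946 H1 H3K18ac regions (0.716%) overlapped a control BrdU region, and the highest-scoring of them, on chromosome 7 at 104652401 to 104656000, overlapped none.

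**Figure D4:**
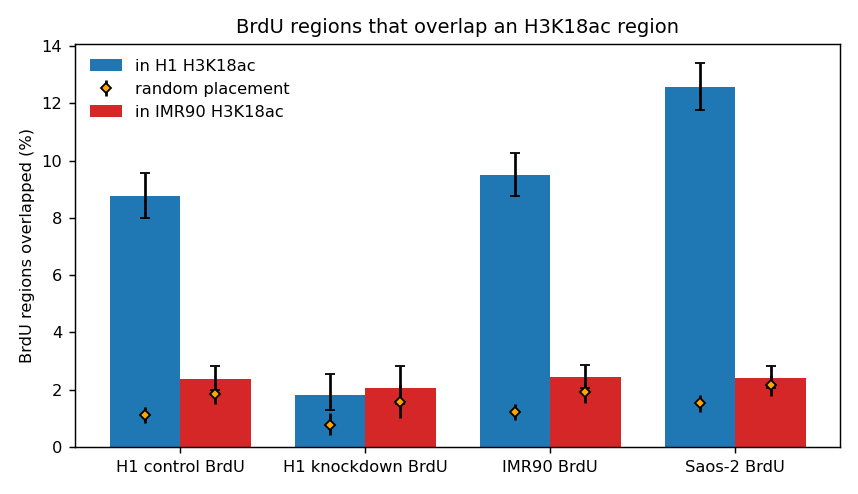
Percent of the regions in each BrdU list that overlap an H3K18ac region of H1 (blue) or IMR90 (red), with Wilson 95% intervals, and the mean and central 95% range of 1000 random placements (orange diamonds). The H1 H3K18ac list lies far above random placement for H1 control, IMR90 and Saos-2 BrdU, at 8.75%, 9.49% and 12.6%, and the IMR90 list stays between 2.05% and 2.44%.

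The fifth comparison asked whether the control BrdU regions that were not called after the knockdown of EP300 and CREBBP were the ones marked by H3K18ac in untreated H1. H3K18ac was found at a smaller share of the lost regions than of the kept ones, but relative to random placement both were alike within counting error. The mark overlapped 415 of the 4930 lost regions (8.42%, 7.67 to 9.23) and 30 of the 156 kept regions (19.2%, 13.8 to 26.1), which was 7.83-fold (7.14 to 8.58) and 8.50-fold (6.11 to 11.5) over placement at their own lengths. The kept regions were, however, the stronger ones, with a median length of 500 bp against 100 bp and a median score of 888 against 71 in the same list. When the lost regions were weighted to the score deciles of the kept regions, 29.8% of them overlapped H3K18ac, and the order of the shares was reversed. When 50% of the region had to overlap, the shares lay within counting error of each other, with 7 kept regions (4.49%) and 260 lost regions (5.27%). Without weighting, the kept share stayed the higher one after merging within 10 kb (43.9% against 23.5%) and with a distance of 10 kb for lost regions (13.2% against 8.31%). In the stricter lists it was higher only within counting error (25 of 146, 17.1%, against 307 of 2397, 12.8%). Of the 10 highest-scoring lost regions 9 overlapped H1 H3K18ac, against 4 of the 10 highest-scoring kept regions. These sets were not matched. The lost ones measured 1600 to 3400 bp with scores of 4127 to 10494, and the kept ones 1200 to 2600 bp with scores of 3072 to 5656. After the knockdown, 32 of the 1755 BrdU regions (1.82%, 1.29 to 2.56) lay in the H1 H3K18ac list, at 2.40-fold (1.70 to 3.37), against 7.88-fold in the control. The lists were not matched for length or score here. The gap was narrower after merging within 10 kb (2.81-fold against 4.34-fold), in 2 kb windows (2.70 against 4.35) and within 1 kb (2.66 against 4.19). It was wider in the stricter lists (3.36 against 14.6). An overlap of 50% gave 2.23 against 6.75, and shifts within 1 Mb gave 1.67 against 4.18. H3K18ac itself was measured in untreated H1 only, so its level after the knockdown was not analysed here.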

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

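The score weighting, the 100 control regions of highest score, the set without regions of all 3 cell lines and the 1 kb distance were chosen after the data had been seen. Autosomes alone left every share and fold that answers a comparison within its interval, and the 59 folds between lists of the same assay stayed between 3.58 and 467. The fold of IMR90 BrdU in IMR90 H3K18ac reversed, from 1.28 to 0.911 in the stricter lists and 0.912 with shifts within 1 Mb. It stayed above 1 under the other 6 alternatives, from 1.29 on autosomes to 1.58 in 2 kb windows, with 1.57 within 1 kb. That of Saos-2 BrdU in the same list, whose interval (0.965 to 1.32) included 1, went from 1.13 to 0.879 in the stricter lists. The cause was not tested for this or for any change below unless stated.

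Requiring 50% overlap lowered, by construction, control in knockdown to 1.08%, control in IMR90 to 16.9% and in Saos-2 to 32.0%, IMR90 in control to 13.9% and in Saos-2 to 24.0%, Saos-2 in control to 18% and in IMR90 to 16.6%, H1 in IMR90 H3K18ac to 15.2% and the reverse to 9.82%, and H3K18ac at kept regions to 4.49% and at lost regions to 5.27%. In the stricter lists these became 5.74% (knockdown in control 17.0%), 39.4%, 60.0%, 34.9%, 43.9%, 45.6%, 37.7%, 22.2% and 16.8%, and 12.8% at lost regions. Merging within 10 kb gave 3.82% for control in knockdown, 21.8% for control in IMR90, 20.1% and 28.3% for IMR90 in control and Saos-2, 29.9% and 26.7% for Saos-2 in control and IMR90, 27.9% and 36.5% for H3K18ac, and 43.9% at kept and 23.5% at lost regions. With as many control as knockdown regions, 7.92% of control regions lay in the knockdown list, and 34% of the highest 100. With lists of equal number, IMR90 in control and Saos-2 reached 20.4% and 29.2%, and Saos-2 in control and IMR90 31.7% and 27.8%. Lists were cut to equal number by keeping the highest scores, so these shares also reflect the selection of strong regions.

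The fold of H1 control in H1 H3K18ac was 6.75 at 50% overlap, 14.6 in the stricter lists, 4.34 after merging, 4.18 with shifts, 4.35 in 2 kb windows, 5.88 without regions of all 3 cell lines and 4.19 within 1 kb. The fold of IMR90 BrdU was 13.0, 4.12, 3.33, 4.47, 6.14 and 4.33 under the same settings from the stricter lists onward, and the knockdown fold was 1.67 with shifts. H3K18ac at kept regions was 13.2% with the 10 kb distance, and at lost regions 29.8% after score weighting. Of the other values, 54 stayed within their interval and 90 moved beyond it, the Saos-2 fold above among them. The gene-list counts and their alternative were not run. Depth is unknown, and it limits what absence from a list means.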

Other observations

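The tests of the knockdown list, of signal common to all libraries, of sequence preference and of marking in the same cell line were chosen after the results were seen, and those of distal chromosome ends beforehand. BrdU regions were concentrated near the ends of the long arms, which was not part of the comparisons, and short-arm ends were not examined. The distal 5 Mb of the long arms make up 4.12% of the genome open to placement and held 15.0% (14.0 to 16.0) of the H1 control regions, 19.3% of those in IMR90, 22.3% of those in Saos-2 and 8.72% (7.49 to 10.1) of those in the knockdown. The H1 H3K18ac list had 12.1% of its regions there and the IMR90 H3K18ac list 4.19%, close to the genome share. Chromosome 19, with 56 of the 2794 Mb open to placement, carried 8.48% of the Saos-2 BrdU regions and 6.32% of those in IMR90. It carried 4.80% of those in H1 control and 2.85% of those in the knockdown. For H3K18ac it carried 5.19% of the H1 and 2.15% of the IMR90 regions.

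At the scale of 1 Mb, each BrdU list was more closely related in region number to H1 than to IMR90 H3K18ac. Across 2877 bins, which are not independent replicates, the Spearman correlation of BrdU with H1 H3K18ac was 0.667 for H1 control, 0.727 for IMR90, 0.581 for Saos-2 and 0.452 for the knockdown. With IMR90 H3K18ac it was 0.299, 0.459, 0.191 and 0.247 in the same order. Within 10 kb, 62.7% of the H1 control regions and 66.9% of the IMR90 BrdU regions had an H1 H3K18ac region, against random shares of 29.2% and 30.9%. The knockdown regions had one in 50.7%, against 27.6%. An IMR90 H3K18ac region lay within 10 kb of 29.2% of H1 control, 30.35% of IMR90 and 29.6% of knockdown BrdU regions. The random shares were 22.9%, 23.6% and 22.1%, so a smaller excess was present for that list too.

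Strong BrdU regions recurred across the cell lines. Clustering at the ends of the long arms as the whole account was argued against by a test outside their distal 5 Mb. There, 717 of 751 regions of the highest H1 control score bin (95.5%, 93.7 to 96.7) still overlapped Saos-2. Short-arm ends stayed in the tested set, so clustering there was not tested. Reads piling up at the same places in every library would put the recurring regions in both H3K18ac lists, if all lists were called alike. How the inputs and thresholds were used is unknown, so this cannot exclude a pile-up removed from 1 list. The fold of H1 control regions of all 3 cell lines was 0.768 (0.481 to 1.22) in the IMR90 list. It was 12.7 (11.2 to 14.2) in the H1 list, so a pile-up common to the BrdU libraries and that of H1 H3K18ac stays open. A sequence preference of the pull-down or of random priming stays open, because 34 of the 100 highest-scoring control regions (25.5% to 43.7%) recurred in the short knockdown list and the inputs were not analysed here, and replication starting at the same sites in all 3 cell lines stays open as well, as untested.

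The H1 H3K18ac list overlapped the BrdU regions of every cell line. Marking of the loci that replicate in H1 itself was examined in the 1000 highest-scoring regions found in H1 only. Their fold of 4.30 (3.23 to 5.71) lay below those of as many regions found in IMR90 only, 7.09 (5.85 to 8.55), or in Saos-2 only, 7.26 (6.19 to 8.49). This order cannot decide the question, because the sets were not matched for score bin. Of the highest bins, 95.7% of H1 control and 84.1% of IMR90 regions overlapped Saos-2, and 71.1% of Saos-2 regions overlapped H1 control. Fewer strong regions were thus left in the H1-only set. H3K18ac overlap of H1 control regions rose from 1.38% in the lowest bin to 30.0% in the highest. The overlap was, however, not confined to regions called in H1. A common preference for the distal ends of the long arms, as the whole account, was argued against by H1 control regions outside them. Their fold was 7.66 (6.93 to 8.47), and short-arm ends stayed in this set. A preference of this H3K18ac list for loci prone to BrdU signal in any cell line, through open or GC-rich DNA or through replication common to the cell lines, stays open and was not tested.

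The knockdown list was short and shared little with the control. A higher threshold on the same signal, as the whole account, would leave most knockdown regions inside the control list, and 9.06% (7.80 to 10.5) were, although 41.0% of its highest score bin and 76 of its 100 highest-scoring regions were. A lower number of reads stays open, since depth is unknown. Weaker signal over a similar background may contribute. Of the 1053 regions in the lower 3 score bins of the knockdown list, 8 (0.760%, 0.385 to 1.49) overlapped any other BrdU list. The highest knockdown bin overlapped Saos-2 alone in 59.5%. In the lower 3 bins of the control list the share was 7.14% (6.28 to 8.11), but in its lower 2 bins it was 1.08%. Regions of low score thus overlapped little in both lists. Bins are ranks within a list, so the contrast cannot decide this. Less BrdU incorporation after the knockdown, for which 34% of the 100 highest-scoring control regions remaining is the nearest value, cannot be told apart from a poorer pull-down with 1 library per condition.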
